A study of Xenopus laevis with 6 samples.

How the data were processed

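The 6 samples were total RNA of embryonic pancreas, liver and stomach buds at stage 42, hybridised to Affymetrix Xenopus laevis genome arrays, 2 arrays for each of 3 organs. The authors deposited 1 table of intensity values on a linear scale, 1 column per array. RMA is named in the submitters' processing notes, without a version, and the series' design text names the Expressionist software of GeneData for refining the data; other steps are not given in the sources used here. The intensities ran from 0.105 to 23202, the median over all 15611 rows was 100 on every array, and the quantiles differed between arrays (95th percentiles from 1243 to 1531), so the values had been scaled to a common median and were not equal in distribution. The table carried no detection calls or background values, so no probe set could be classed as above or below background. In all, 11.9% to 13.7% of the probe sets of an array were under an intensity of 16. The series' design text states 4202 genes with an ANOVA p under 0.05, and a plain ANOVA of log2 intensities over all 15611 rows, controls included, had 4202 rows under that limit.

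Arrays were assigned to organs and replicate numbers from their titles. The titles call the 2 samples of an organ numbers 1 and 2, and all samples of 1 number share an experiment code, so the number marks a shared batch that holds all 3 organs. Deviations from the organ means correlated between organs within a number at 0.197 for pancreas and stomach, 0.173 for pancreas and liver and 0.152 for stomach and liver across probe sets, and at 0.417 or more for probe sets with a mean over 100; the third principal component, with 12.0% of the variance, separated the numbers. No probe set was called between the numbers in the additive model by limma. The numbers were therefore taken to pair the samples, and a fit with the replicate number as a block was run as an alternative. The design text calls the isolations independent; how many embryos each held is not given in the sources used here.

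Control rows were left out (120), which left 15491 probe sets. Gene names came from the platform annotation supplied with the data: 9304 probe sets had 1 gene symbol, 195 had several and 5992 had none; 9227 of the 9304 were found by gene identifier in a RefSeq gene table of the Xenopus laevis v10.1 assembly, and 2 symbols were updated. Symbols ending in .L and .S are the copies of a gene on the long and short chromosomes of this allotetraploid frog and counted as separate genes, 7531 in all. No coordinates are printed, since the arrays name no genome build. Where a gene had several probe sets (1293 genes), the one with the highest mean over the 6 arrays stood for it, and others that disagreed in sign or call are stated. A disagreement counts if it occurred for any pair of organs, which need not be the pair named.

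The main analysis used log2 of the deposited intensities in limma 3.58.1 under R 4.3.3: lmFit with organ means on all 6 arrays, contrasts.fit and eBayes, with Benjamini-Hochberg adjustment per contrast and a threshold of 0.05. It had 3 residual degrees of freedom and a prior of 2.14. An organ-enriched probe set had an adjusted p under 0.05 and a ratio above 3 against both other organs; a set enriched in 2 organs met this in both of them against the other one and was not in a 1-organ class. An exact permutation test of 2 arrays against 2 cannot go below p = 0.333, so single genes rest on limma, and p-values measure the spread between the 2 isolations. Means ± SD are of linear intensities, and folds are ratios of geometric means.

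Before the data were examined, 22 gene lists were fixed. Each was tested in each organ against the mean of the other 2 with limma's camera, adjusted over 66 tests. The preset correlation was 0.01. Alternatives were fry and camera with an estimated correlation, which called no list (lowest adjusted p 0.176), including lists with a negative estimate. As that camera setting called no list at all, its adjusted p, printed beside the lists, cannot decide on any single list. Counts "adjusted over the list alone" apply the adjustment to the members of 1 list. Older names were matched through synonyms, and 6 matches that belonged to other genes were left out before any list value was seen. The genes named in the text (151) follow a rule fixed at the same time: the 10 largest by the smaller of the 2 folds in each 1-organ class, the 4 largest in each 2-organ class, the 5 largest per direction of each pair with both arrays of an organ above both of the other, and up to 4 called members per list and organ (if none, the 2 with the highest mean). Other genes are named only where a list's few called members are given or in the closing section, and were chosen after their values were seen.

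Other alternatives were each array left out in turn, a filter that left out probe sets under the 40th percentile of mean intensity, quantile normalization, a common median, log2 of the intensity plus 16, an intensity trend with a robust prior, only the 4 arrays of a pair, the plain ANOVA of the methods, K-means with 6 clusters as in the design text (50 starts), ratios of 2 and 5, genes in place of probe sets, and the mean of a gene's probe sets. Where leaving out an array left an organ with 1, that array was assumed to vary like the others. In data simulated from the 15491 probe sets, 200 were changed in pancreas. The rule for the pancreas class recovered 6.57% of those changed by 3-fold and 55.2% of those changed by 8-fold, and the F test 0 at 2-fold. Of the F calls 2.41% were false, and unchanged organs gave no calls in 5 simulations. Noise was drawn independently for each probe set and array, without the correlation within a replicate number seen in the data. The false share and the lack of calls describe only that setting. Another simulation kept the organ means of the data. Of 153 probe sets with a mean over 100 and over 8-fold between pancreas and liver, either way, it called 146 (95.4%) between these organs. The shares recovered with 200 changed are therefore not those of the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.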

Results

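RNA from pancreas, liver and stomach buds of Xenopus laevis embryos at stage 42, a swimming tadpole stage, was measured on 6 Affymetrix Xenopus laevis genome arrays. Each organ had 2 arrays, from 2 independent isolations of tissue, and replicates 1 and 2 below stand for the isolations. The study asked which genes the developing pancreas expresses above its neighbouring organs. The table held 15611 rows, of which 15491 were probe sets of genes, and the median intensity of each array was 100. Arrays of 1 organ correlated at Pearson r of 0.955 for pancreas, 0.946 for liver and 0.952 for stomach across log2 intensities, and arrays of different organs at 0.850 to 0.904. These correlations run across genes, which are not independent replicates. With 2 arrays per organ, the number of arrays limits the precision of every value. The median residual SD was 0.287 on the log2 scale, and it ranged from 0.851 for probe sets with a mean intensity under 16 to 0.166 for those over 1000.

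Genes of each organ's known function separated the 3 buds. The insulin gene ins.S was at an intensity of 5641 ± 317 in pancreas, 44.1 ± 6.34 in liver and 56.0 ± 34.3 in stomach (mean ± SD, n = 2). The fibrinogen chain gene fgb.L was at 3913 ± 654 in liver, 28.9 ± 31.5 in pancreas and 2.52 ± 0.269 in stomach. The gene of the gastric proton pump's beta subunit, atp4b.S, was at 4703 ± 3450 in stomach, 50.6 ± 64.3 in pancreas and 14.0 ± 0.757 in liver. The limma moderated F test called 1960 probe sets as differing among the organs at an adjusted p under 0.05, and 4846 had an unadjusted p under 0.05. A count of 710 was left without pancreas replicate 1, 830 without pancreas replicate 2, 766 without liver replicate 1, 1034 without liver replicate 2, 487 without stomach replicate 1 and 726 without stomach replicate 2. Folds over low intensities depend on the scale and on single arrays. With 16 added to each intensity, the 94 pair contrasts of genes named for a class or a pair were all called, but the fold changed by over 2 times in 48 of them. Leaving out pancreas replicate 1 or 2 changed it by over 1.5 times in 25 and 24, liver replicate 1 or 2 in 13 each, and stomach replicate 1 or 2 in 8 each. With 2 arrays per organ, leaving out either moves a fold by the same factor in opposite directions. The 2 counts of an organ are therefore 1 check, and contrasts without that organ cannot change.

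**Figure D1:**
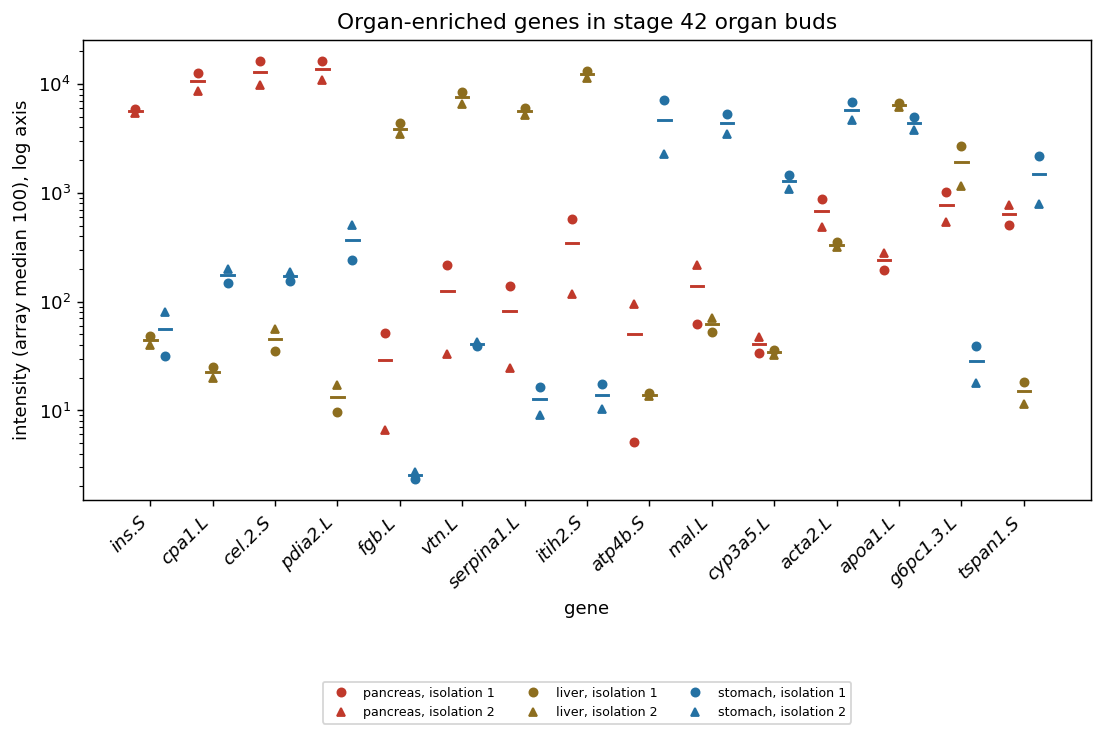
Intensity on a log axis of 15 named genes in the 6 arrays; circles are isolation 1, triangles isolation 2, and short lines the organ means. The pancreas arrays sit at 5865 and 5417 for ins.S, against 31.7 to 80.2 in the stomach arrays, and the liver genes fgb.L, vtn.L and serpina1.L are apart between the pancreas arrays.

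Digestive enzymes and insulin made up most of the genes with the largest pancreas excess. The pancreatic disulfide isomerase gene pdia2.L was 1050-fold higher in pancreas than in liver (log2 difference 10.04, SE 0.493) and 38.7-fold higher than in stomach. Its liver values were 9.59 and 17.04, and with 16 added it was 464-fold higher than in liver. Carboxypeptidase A cpa1.L was 468-fold higher than in liver (273-fold with 16 added) and 60.5-fold higher than in stomach, and the bile-salt-stimulated lipase cel.2.S 283-fold and 73.3-fold. Ranked by the smaller of the 2 folds, the 10 leading genes were cpa1.L and cel.2.S, the other lipase copy cel.2.L, the chitinase chit1.S, the deoxyribonuclease dnase1, amylase amy2b.S, carboxypeptidases cpb1.S and cpa1.S and both insulin genes. The insulin gene ins.S was 129-fold and ins.L 58.9-fold above liver, and they were 112-fold and 63.1-fold above stomach. Without stomach replicate 1 or 2 the fold of ins.S above stomach was 70.3 and 178. The smaller fold was 55.2 for cel.2.L, 19.6 for chit1.S and 12.2 for cpa1.S with 16 added, in place of 159, 117 and 82.1. Without pancreas replicate 1 or 2 cpa1.S was 42.1-fold and 160-fold and amy2b.S 50.1-fold and 176-fold above stomach. Without stomach replicate 1 or 2 amy2b.S was 153-fold and 57.4-fold above it, and without liver replicate 1 or 2 chit1.S was 197-fold and 69.2-fold above liver. Of 2 other probe sets of cpb1.S, 1 differed in call for a pair of organs.

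Of 17 measured exocrine enzyme genes, 12 were higher in pancreas than in the mean of the other organs and none was lower, with a median log2 difference of 6.22 (14 higher when adjusted over the list alone). The list's camera test gave an adjusted p of 7.98e-14, and adjusted p = 0.176 with an estimated correlation. Chymotrypsins ctrl.L and ctrb1.L were at 17900 ± 4360 and 20720 ± 3510 in pancreas (SD, n = 2). In liver 12 of the 17 were lower (median -3.88, adjusted p = 9.56e-12, and adjusted p = 0.176 with an estimated correlation), and in stomach 6 were lower (median -0.75, adjusted p = 0.000484, and adjusted p = 0.241 with an estimated correlation). Several of these transcripts were above liver in stomach: ctrb1.L was 13.1-fold higher in stomach than in liver, pdia2.L 27.3-fold (12.6-fold with 16 added), ctrl.L 8.87-fold and cpa1.L 7.74-fold (4.92-fold with 16 added). For ctrb1.L it was 8.11-fold and 21.3-fold without liver replicate 1 or 2.

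Of 18 endocrine genes, 6 were higher in pancreas (8 adjusted over the list alone), with a camera adjusted p of 0.00387, and adjusted p = 0.222 with an estimated correlation. Besides insulin these included pcsk2.L, a prohormone convertase, 47.0-fold above liver (20.7-fold with 16 added) and 11.4-fold above stomach, and the granule protein gene scg3.L. The gene scg3.L was at 66.9 ± 24.3 in pancreas and 64.7 ± 25.7 in stomach (SD, n = 2), which was not called (limma adjusted p = 0.944). Its call against the mean of the others rests on liver values of 1.84 and 1.77. Under the replicate block 4 of the 18 were higher. In liver 8 of the 18 were lower and pam.L was higher (median -1.43, adjusted p = 4.11e-07, and adjusted p = 0.176 with an estimated correlation). In stomach 4 were higher and 3 lower, 2 under the block (median 0.39, adjusted p = 0.164). Chromogranin chga.L was 5.23-fold higher in stomach than in pancreas and 11.2-fold higher than in liver. The somatostatin gene sst.1.L was at 543 ± 389 in stomach and 74.7 ± 38.2 in pancreas (SD, n = 2). It was higher in stomach than in the mean of the others, with an adjusted p of 0.0517 under the replicate block.

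Among 16 transcription factor genes of pancreas development, 5 were higher in pancreas and none lower (11 adjusted over the list alone; adjusted p = 2.29e-05, and adjusted p = 0.176 with an estimated correlation). The orphan receptor gene nr5a2.L was 4.81-fold above liver and 27.8-fold above stomach (15.7-fold with 16 added). Its other probe set differed in call for a pair of organs. The gene xbp1.L, a regulator of secretory cells, was 6.6-fold above stomach. Above liver it was 1.92-fold higher, which did not pass (limma adjusted p = 0.147). For nr5a2.S, 30.4-fold above stomach (17.2-fold with 16 added, and 18.8-fold and 49.1-fold without stomach replicate 1 or 2), the gene's other probe set had the opposite sign for a called pair of organs. The homeobox gene mnx1.S was higher in pancreas than in the mean of the others (log2 difference 2.03), with an adjusted p of 0.0676 under the replicate block. In liver prox1.L was higher and 3 of the 16 were lower (median -0.68, adjusted p = 0.0440; adjusted p = 0.235 with an estimated correlation and 0.0580 with the replicate block). Under the block 1 was lower, as neurod1.L and gata6.S ended (adjusted p = 0.0560 and 0.0503). In stomach 1 was higher and 4 lower, with an adjusted p of 0.197.

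The pancreas-enriched class, with an adjusted p under 0.05 and a ratio above 3 against both other organs, held 115 probe sets, 85 of them with 1 symbol, for 81 genes. Within replicate 1 alone 112 of the 115 kept a ratio above 3 over both organs, within replicate 2 alone 106, and within both 103. In all, 203 probe sets were higher in pancreas than in both organs. Independent lists would share 15, and part of the excess may come from the pancreas arrays that both contrasts share. Simulated unchanged organs gave no call in any pair, which fixed their class at 0, so they give no comparison. The class fell to 0 without pancreas replicate 1 or stomach replicate 1, where 155 and 157 probe sets met the rule at an unadjusted p under 0.05, against 163 with all arrays. It held 31 without pancreas replicate 2, 33 without liver replicate 1, 61 without liver replicate 2 and 38 without stomach replicate 2.

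Genes of blood plasma proteins had the largest liver excess. Fibrinogen fgb.L was 211-fold higher in liver than in pancreas (log2 difference -7.72 for pancreas minus liver, SE 0.945) and 1550-fold higher than in stomach. The kininogen gene kng1.L was 149-fold above pancreas and 705-fold above stomach, heparin cofactor serpind1.S 248-fold and 194-fold, and prekallikrein klkb1.L 372-fold and 231-fold. Fibrinogen fga.L, ptgds-b, hpd-like.2.L, the protease inhibitor gene serpina1.L, coagulation factor f12.L and vitronectin vtn.L followed, between 87.7-fold and 142-fold above pancreas and between 94.7-fold and 922-fold above stomach. Several of these folds rest on values near the lowest intensities, such as 2.33 and 2.71 for fgb.L and 1.6 and 1.66 for hpd-like.2.L in stomach. With 16 added the folds above pancreas and stomach were 100 and 211 for fgb.L, 100 and 236 for kng1.L, 79 and 85.6 for serpind1.S and 65.2 and 63.7 for klkb1.L. They were 55.1 and 97.6 for fga.L, 43.5 and 86.2 for hpd-like.2.L and 70.8 and 197 for serpina1.L, while f12.L was 57.9-fold above pancreas and ptgds-b 132-fold above stomach. The fold above pancreas of all 10 genes depended on the pancreas array. Without replicate 1 or 2 it was 587 and 76 for fgb.L, 286 and 77.5 for kng1.L, 893 and 69 for serpind1.S, 1400 and 99 for klkb1.L, 441 and 45.8 for fga.L, 346 and 49.1 for ptgds-b, 409 and 32.6 for hpd-like.2.L, 227 and 40.4 for serpina1.L, 283 and 32.7 for f12.L and 225 and 34.2 for vtn.L. Without replicate 2 the pancreas calls of klkb1.L, fga.L and ptgds-b ended (adjusted p = 0.0660, 0.0580 and 0.0552). Without liver replicate 1 or 2 the folds above pancreas and stomach were 85.4 and 368 or 237 and 1020 for fga.L, and 80.1 and 128 or 212 and 340 for ptgds-b. Without stomach replicate 1 or 2 klkb1.L was 462-fold and 115-fold above stomach. The other probe set of kng1.L and that of fga.L each differed in call for a pair of organs.

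Of 45 plasma protein genes, 38 were higher in liver and none lower, with a median log2 difference of 5.12 (41 higher adjusted over the list alone; adjusted p = 7.33e-34, and adjusted p = 0.176 with an estimated correlation). In pancreas 14 were lower and none higher (median -2.16, adjusted p = 1.64e-17, and adjusted p = 0.222 with an estimated correlation). In stomach 23 were lower and 2 higher (median -2.92, adjusted p = 7.84e-13, and adjusted p = 0.224 with an estimated correlation). The liver excess by itself lowers pancreas and stomach against the mean of the others. The 2 that were higher in stomach were the apolipoprotein genes apoa1.L, at 4391 ± 845 in stomach and 6425 ± 318 in liver, and apob.S, at 1456 ± 200 and 3708 ± 164 (SD, n = 2). Between the pancreas arrays 36 of the 45 were higher in replicate 1 and 9 in replicate 2. The gene vtn.L was at 219 in replicate 1 and 33.3 in replicate 2 and itih2.S at 578 and 119, whereas apoa1.L was at 196 and 283.

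Of 31 liver metabolism genes, 9 were higher in liver and 1, acaa2.L, was lower (13 and 1 adjusted over the list alone; adjusted p = 2.13e-06, and adjusted p = 0.242 with an estimated correlation). The glycolate oxidase gene hao1.L was 23.7-fold above pancreas and 32.0-fold above stomach, the tyrosine-degrading fah.L 17.6-fold and 27.6-fold, and the aminotransferase gene agxt.L 5.52-fold and 124-fold. In pancreas 2 were higher, the histidine-degrading enzyme genes uroc1.L and ftcd.L, and 2 were lower, hao1.L and fah.L (median 0.14, adjusted p = 0.874); fah.L had an adjusted p of 0.0628 under the replicate block. In stomach 10 were lower and 1 higher (median -1.34, adjusted p = 3.38e-06, and adjusted p = 0.242 with an estimated correlation).

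Blood cell genes moved with the liver. Of 20 erythrocyte genes 7 were higher there (9 adjusted over the list alone; median 1.25, adjusted p = 1.13e-07, and adjusted p = 0.176 with an estimated correlation), among them the globin genes hba2.L, 4.63-fold above pancreas and 7.08-fold above stomach, and hba-l5.L. In stomach 6 were lower (median -0.997, adjusted p = 2.88e-05, and adjusted p = 0.176 with an estimated correlation). In pancreas the list did not pass (median -0.28, adjusted p = 0.0751, and adjusted p = 0.289 with an estimated correlation), and with the replicate block it passed as lower (adjusted p = 0.0381). Its 1 called member, bpgm.S, went the other way, 17.8-fold above stomach (6.09-fold with 16 added). Of 23 leukocyte genes 8 were higher in liver and 1 lower (median 0.73, adjusted p = 0.00261, and adjusted p = 0.224 with an estimated correlation). Myeloperoxidase mpo.L was 7.13-fold above pancreas and 12.8-fold above stomach, while the galectin gene lgals3.L was 19.6-fold higher in stomach than in liver. The leukocyte list was lower in pancreas (1 gene, ctss.S; median -0.60, adjusted p = 0.00243, and adjusted p = 0.224 with an estimated correlation), and in stomach 3 were higher and 7 lower (adjusted p = 0.398). Of 14 endothelial genes 4 were higher in liver and 4 lower in stomach, among them aplnr.S and sox18.L, with adjusted p of 8.50e-05 and 0.000124, each with adjusted p = 0.224 with an estimated correlation; none was called in pancreas (adjusted p = 0.697).

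The liver-enriched class held 263 probe sets, 166 with 1 symbol, for 159 genes by any probe set, and 237 of the 263 had a ratio above 3 over both organs within both isolations (255 within replicate 1 and 245 within replicate 2). Higher than both organs were 354 probe sets, against 27.2 for independent lists, with the liver arrays shared by both contrasts. The class held 109 without pancreas replicate 1, 62 without pancreas replicate 2, 41 without liver replicate 1, 142 without liver replicate 2, 125 without stomach replicate 1 and 151 without stomach replicate 2.

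Genes of the gastric epithelium and of the muscular wall were higher in stomach. The proton pump gene atp4b.S was 182-fold higher than in pancreas and 288-fold higher than in liver, and the aspartic protease gene ctse.S 95-fold and 103-fold. Under the replicate block their adjusted p against pancreas were 0.0694 and 0.0715, and against liver 0.0596 and 0.0695. The transcription factor gene sox2.L, a marker of the anterior gut, was 48.8-fold above pancreas and 118-fold above liver (log2 differences -5.61 and -6.89, SE 0.990). Its other probe set differed in call for a pair of organs. The fatty acid binding protein gene fabp2.L was 43.3-fold and 191-fold higher, and cnfn.1.L, gsto1.S, mal.L, ag1.L, cyp3a5.L and fut6.S between 31.7-fold and 50.9-fold above pancreas and between 28.0-fold and 107-fold above liver. With 16 added the folds above pancreas and liver were 83.1 and 135 for atp4b.S, 32.1 and 33.2 for ctse.S, 21.8 and 35.4 for sox2.L and 11.7 and 9.28 for fut6.S, and fabp2.L was 92.9-fold above liver. Without pancreas replicate 1 or 2 the fold above pancreas was 41.9 and 788 for atp4b.S, 37.3 and 242 for ctse.S, 16.6 and 143 for sox2.L and 28.9 and 65 for fabp2.L, and between 18.2 and 123 for cnfn.1.L, gsto1.S, mal.L and ag1.L. Without liver replicate 1 or 2 the fold above liver was 256 and 41.1 for ctse.S and 64.4 and 12.2 for fut6.S. Without stomach replicate 1 or 2 atp4b.S was 102-fold and 323-fold above pancreas and 162-fold and 512-fold above liver. Between the pancreas arrays ag1.L was at 95.7 in replicate 1 and 351 in replicate 2 and mal.L at 61.7 and 217, whereas tspan1.L was at 419 and 330.

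Of 22 stomach epithelium genes 10 were higher in stomach and none lower (13 and 1 adjusted over the list alone; median 2.35, adjusted p = 6.65e-07, and adjusted p = 0.222 with an estimated correlation), among them agr2.S, 8.22-fold above pancreas and 84.4-fold above liver, and vsig1.L, 16.7-fold and 9.13-fold (5.89-fold and 4.7-fold with 16 added). Without liver replicate 1 or 2 agr2.S was 51.8-fold and 137-fold above liver, and 53-fold with 16 added. Under the replicate block 7 were higher in stomach, as atp4b.S, ctse.S and sst.1.L ended against the mean of the others (adjusted p = 0.0504, 0.0545 and 0.0517). In liver 5 were lower, 4 under the block (median -1.57, adjusted p = 1.16e-05, and adjusted p = 0.222 with an estimated correlation), and in pancreas 1 was lower (median -0.85, adjusted p = 0.0691). Between the pancreas arrays 11 of the 22 were higher in replicate 1 and 11 in replicate 2. Of 25 smooth muscle genes 14 were higher in stomach and none lower (18 adjusted over the list alone; median 1.88, adjusted p = 7.84e-13, and adjusted p = 0.176 with an estimated correlation). Smooth muscle actin acta2.L was 8.68-fold above pancreas and 16.9-fold above liver, at 5779 ± 1600 in stomach (SD, n = 2), and the myosin heavy chain gene myh11.S 17.7-fold and 52.0-fold. Above liver myh11.S was 23.1-fold higher with 16 added, and 122-fold and 22.2-fold without liver replicate 1 or 2. The list was lower in pancreas (2 genes, foxf1.L and tpm1.L, median -1.08, adjusted p = 2.49e-07) and in liver (7 genes, median -0.72, adjusted p = 0.000466), with adjusted p = 0.222 and adjusted p = 0.242 with an estimated correlation. The stomach excess by itself lowers pancreas and liver against the mean of the others. A muscle actin control row of the arrays was at 1848 and 1683 in the stomach arrays, 190 and 180 in pancreas and 382 and 203 in liver.

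Neuronal genes and parts of the extracellular matrix were also higher in stomach. Of 27 genes of neurons and glia 9 were higher and none lower (15 adjusted over the list alone; median 1.12, adjusted p = 2.07e-08, and adjusted p = 0.176 with an estimated correlation). The synaptic vesicle gene syt1.L was 27.2-fold above pancreas and 26.8-fold above liver. Under the replicate block 7 were higher in stomach, as nos1.L and prph.S ended (adjusted p = 0.0520 and 0.0687). That list was lower in pancreas, with 1 gene higher and 2 lower (median -0.49, adjusted p = 0.00307), and in liver, with 4 lower and 3 under the block (median -0.46, adjusted p = 0.00129), each with adjusted p = 0.222 with an estimated correlation. Here too the stomach excess by itself lowers both organs against the mean of the others. Under the replicate block the pancreas calls of scg2.L and syt1.L ended (adjusted p = 0.0535 and 0.0508). Of 27 matrix genes 4 were higher in stomach and 1 lower (median 0.18, adjusted p = 0.0473, and adjusted p = 0.358 with an estimated correlation). The gene col6a1.L was 5.29-fold above pancreas, and col3a1.S 5.67-fold, while the 2 other probe sets of col3a1.S differed in call for a pair of organs. In pancreas the matrix list was lower (median -0.40, adjusted p = 0.00499, and adjusted p = 0.242 with an estimated correlation). Of its members col5a1.L was lower and loxl1.L and sparc.L were higher, but both higher calls ended under the replicate block (adjusted p = 0.0515 each), where none was higher and 4 were lower. In liver 3 were higher and 1 lower (adjusted p = 0.801), of which vim.L and the lower sparc.L ended under the block (adjusted p = 0.0510 and 0.0579). Fibronectin fn1.S was 7.15-fold higher in liver than in stomach, although its 3 other probe sets differed in call for a pair of organs.

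The stomach-enriched class held 298 probe sets, 189 with 1 symbol, for 185 genes, of which 247 had a ratio above 3 within both isolations (284 within replicate 1 and 260 within replicate 2). Higher than both organs were 404, against 31.6 for independent lists, with the stomach arrays shared by both contrasts. The class fell to 0 without pancreas replicate 1 or stomach replicate 1 (403 and 376 at an unadjusted p under 0.05, against 428 with all arrays), and held 100 without pancreas replicate 2, 136 without liver replicate 1, 192 without liver replicate 2 and 92 without stomach replicate 2.

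**Figure D2:**
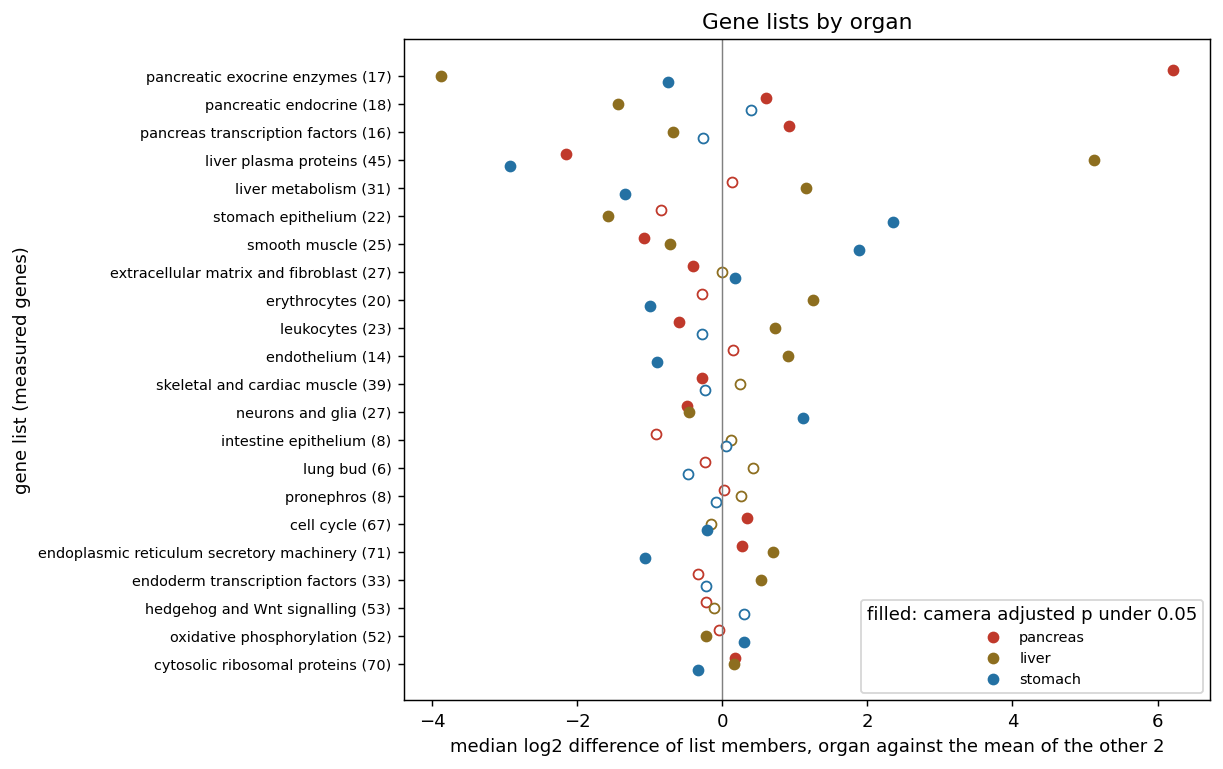
Median log2 difference of the members of 22 gene lists in each organ against the mean of the other 2 organs; filled points had a camera adjusted p under 0.05 with the preset correlation. Exocrine enzymes lie at 6.22 in pancreas, plasma proteins at 5.12 in liver, and stomach epithelium and smooth muscle at 2.35 and 1.88 in stomach.

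Pairs of organs shared smaller sets of genes. Pancreas and liver were above stomach for the cysteine dioxygenase gene cdo1.L (114-fold and 131-fold), the glucose-6-phosphatase gene g6pc1.3.L (27.9-fold and 67.1-fold), nr5a2.S and prox1.L (8.47-fold and 14.1-fold). Pancreas and stomach were above liver for tspan1.S (43.2-fold and 90.3-fold), scg3.L (35.8-fold and 34.4-fold), rgma.L (15.2-fold and 40-fold) and darmin.L (56.0-fold and 14.6-fold). With 16 added the folds were 40.2 and 46 for cdo1.L, 17.5 and 41.5 for g6pc1.3.L, 17.2 and 5.76 for nr5a2.S, 20.9 and 43.2 for tspan1.S, 4.56 and 4.42 for scg3.L, which was at 1.84 and 1.77 in liver, 6.95 and 17.4 for rgma.L and 14.4 and 4.32 for darmin.L. Without pancreas replicate 1 or 2 pancreas was 72.8-fold and 179-fold above stomach for cdo1.L, and 86.2-fold and 36.4-fold above liver for darmin.L. Without liver replicate 1 or 2 liver was 61-fold and 280-fold above stomach for cdo1.L and 43.8-fold and 103-fold for g6pc1.3.L, and the folds above liver of rgma.L were 25 and 65.9 or 9.24 and 24.3. Without stomach replicate 1 or 2 stomach was 54.1-fold and 151-fold above liver for tspan1.S, and pancreas 18.8-fold and 49.1-fold above stomach for nr5a2.S. Liver and stomach were above pancreas for apoa1.L (27.3-fold and 18.5-fold), apob.S (32.3-fold and 12.6-fold), gstt1.L (14.1-fold and 15.8-fold) and the retinoic acid-degrading enzyme gene cyp26a1.L, at 7.21 ± 2.38 in pancreas, 143 ± 15.4 in liver and 125 ± 51.4 in stomach (SD, n = 2).

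These classes held 80 probe sets for pancreas and liver, 70 for pancreas and stomach and 56 for liver and stomach, for 54, 44 and 34 genes, and 56, 56 and 46 of them had a ratio above 3 within both isolations. All 6 classes together held 882 probe sets, of which 54 met both a 1-organ and a 2-organ rule and were counted in the former. Without pancreas replicate 1 and without stomach replicate 1 the pancreas-and-liver class held 0 (107 and 206 at an unadjusted p under 0.05) and the liver-and-stomach class 0 (183 and 109). The pancreas-and-liver class held 22 without pancreas replicate 2, 50 and 55 without liver replicates 1 and 2, and 21 without stomach replicate 2. The liver-and-stomach class held 16, 11, 20 and 17 in that order. The pancreas-and-stomach class held 25 and 13 without pancreas replicates 1 and 2, 13 without liver replicate 1, 34 without stomach replicate 1 and 44 without stomach replicate 2. The series' design text gives 120 genes for pancreas, 237 for liver, 303 for stomach, 90 for pancreas and liver, 88 for pancreas and stomach and 74 for liver and stomach, 912 in all, after redundant entries were removed by hand. The classes here count probe sets by another rule.

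**Figure D3:**
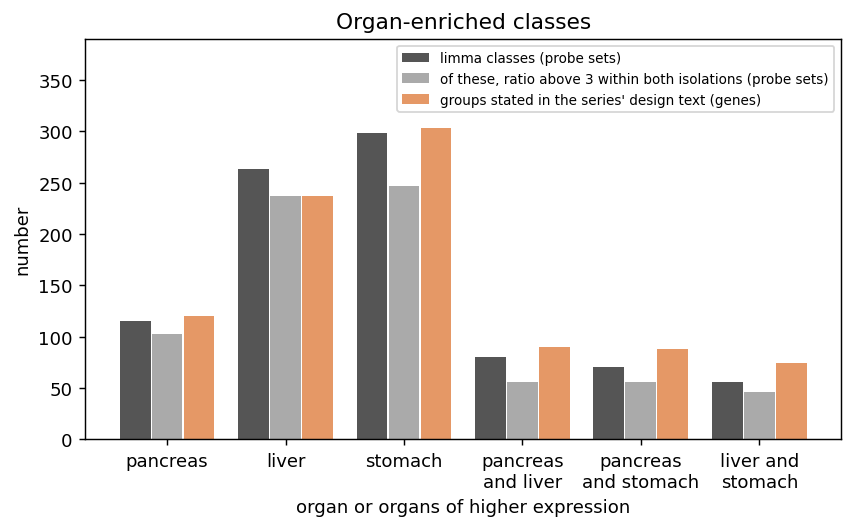
Number of probe sets in the 6 classes (dark bars), of those with a ratio above 3 within both isolations (light bars), and of genes in the groups that the series' design text states (orange bars). The pancreas class has 115 probe sets beside 120 stated genes, the liver class 263 beside 237, and the stomach class 298 beside 303.

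The binding protein gene stxbp6.L led pancreas over stomach at 224-fold, over stomach values of 9.46 and 9.21 (83.2-fold with 16 added), and the cilium genes rsph1.L, rsph3.L and ccdc63.L were 121-fold, 81.5-fold and 80.5-fold higher in stomach than in pancreas. Their pancreas values were 1.38 to 5.48, near the lowest intensities, and with 16 added the folds were 26.9, 8.59 and 12.3. Without pancreas replicate 1 or 2 ccdc63.L was 40.4-fold and 160-fold higher. Between liver and stomach, itih2.S was 923-fold higher in liver, and tspan1.L, lgals4.1.s and ctse.L were 388-fold, 149-fold and 146-fold higher in stomach. With 16 added the folds were 416 for itih2.S, 122 for tspan1.L, at 13.87 and 4.22 in liver, 27.6 for lgals4.1.s, at 1.88 and 7.08 in liver, and 87.7 for ctse.L. Without liver replicate 1 or 2 they were 704 and 214 for tspan1.L and 76.9 and 290 for lgals4.1.s. Pancreas and liver differed for 969 probe sets, with 419 higher in pancreas and 550 in liver, of which 265 and 424 by over 3-fold. Pancreas and stomach differed for 1236, with 556 higher in pancreas and 680 in stomach, of which 295 and 485 by over 3-fold. Liver and stomach differed for 1485, with 766 higher in liver and 719 in stomach, of which 509 and 520 by over 3-fold. The pancreas and liver count was 198 and 137 without pancreas replicates 1 and 2, 105 and 334 without liver replicates 1 and 2, and 552 without either stomach array. The pancreas and stomach count was 0 in limma without pancreas replicate 1 or stomach replicate 1, where 2819 and 2815 had an unadjusted p under 0.05, 211 without pancreas replicate 2, 196 without stomach replicate 2 and 731 without either liver array. The liver and stomach count was 466 and 750 without liver replicates 1 and 2, 303 and 509 without stomach replicates 1 and 2, and 966 without either pancreas array.

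Hedgehog and Wnt pathway genes differed between the buds in both directions. The ligand gene shh.L was low in pancreas, at 12.6 ± 2.09 against 187 ± 76.0 in liver and 108 ± 17.2 in stomach (SD, n = 2), which was 14.3-fold and 8.58-fold lower (6.84-fold and 4.33-fold with 16 added). The Wnt antagonist gene sfrp2.S was 10.7-fold higher in stomach than in pancreas and 11.1-fold higher than in liver, and wnt5a.S and dhh.L were 11.9-fold and 8.51-fold above pancreas (3.25-fold and 2.89-fold with 16 added). The Wnt receptor gene fzd10.S was 4.34-fold and 9.01-fold higher in pancreas than in liver and stomach (5.97-fold for stomach with 16 added). The other probe set of fzd10.S differed in call for a pair of organs. The Wnt target axin2.L was 7.31-fold higher in liver than in stomach. Of 53 measured genes 1 was higher and 2 lower in pancreas, 2 and 3 in liver, and 6 and 6 in stomach, and no organ's list passed the test (adjusted p = 0.130, 0.850 and 0.0615).

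Of 33 endoderm transcription factor genes, 5 were higher and 1 lower in pancreas, 6 and 2 in liver (6 and 1 under the replicate block), and 3 and 6 in stomach. The forkhead gene foxa4.S, at 12 and 21.8 in pancreas and 1.43 and 0.983 in stomach, was higher in pancreas at near-lowest intensities (log2 difference 3.77, and 0.919 with 16 added). The related gene foxa1.S was 5.48-fold higher in stomach than in pancreas. The gene hnf4a.S, a hepatocyte regulator, was 5.14-fold and 5.85-fold higher in liver than in pancreas and stomach. Its other probe set differed in call for a pair of organs. The liver bud gene hhex.L was 22.3-fold above pancreas (adjusted p = 0.0467; 6.16-fold with 16 added, and 54.5-fold and 9.11-fold without pancreas replicate 1 or 2) and 13-fold above stomach in mean, which did not pass (adjusted p = 0.0593). Only the liver list passed the test (median 0.53, adjusted p = 0.0473; adjusted p = 0.224 with an estimated correlation and 0.0529 with the replicate block); pancreas and stomach had adjusted p of 0.398 and 0.161.

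Genes of the secretory pathway in the endoplasmic reticulum were lower in stomach. Of 71 measured, 34 were lower in stomach and none higher (median -1.06, adjusted p = 2.01e-19, and adjusted p = 0.224 with an estimated correlation), and 57 were lower adjusted over the list alone. In liver 15 were higher and none lower (39 adjusted over the list alone; median 0.70, adjusted p = 1.54e-16, and adjusted p = 0.241 with an estimated correlation), among them pdia4.L, 5.5-fold above pancreas and 5.52-fold above stomach, and calr.L, 4.01-fold and 3.32-fold. In pancreas 4 were higher and 2 lower (median 0.27, adjusted p = 0.0330, and adjusted p = 0.708 with an estimated correlation). The translocation gene sec62.S was 3.79-fold above stomach, and xbp1.L was among the higher genes.

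Cell cycle genes showed small differences. Of 67, the kinetochore gene ndc80.S and the cyclin gene ccne1.S were higher in pancreas (median of the list 0.34, adjusted p = 0.000436, and adjusted p = 0.487 with an estimated correlation), and none adjusted over the list alone. In liver 1 was higher, mcm6.L, at 1.84 ± 0.679 (SD, n = 2), near the lowest intensities (list adjusted p = 0.168). In stomach 1 was lower, cdk2.S, with an adjusted p of 0.0521 under the replicate block (median of the list -0.22, adjusted p = 0.0473, and adjusted p = 0.702 with an estimated correlation).

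No member of the 52 oxidative phosphorylation genes or of the 70 cytosolic ribosomal protein genes was called in any organ by the main limma fit. With 16 added 7 of the oxidative phosphorylation genes were higher in stomach. Oxidative phosphorylation genes had a median of 0.30 in stomach (adjusted p = 3.58e-06, and adjusted p = 0.487 with an estimated correlation), -0.23 in liver (adjusted p = 0.000815, and adjusted p = 0.632 with an estimated correlation) and -0.04 in pancreas (adjusted p = 0.210). The subunit gene atp5f1a.L was at 9491 ± 1640 in pancreas, 9429 ± 1340 in liver and 9970 ± 125 in stomach (SD, n = 2). Ribosomal protein genes had medians of 0.18 in pancreas, 0.16 in liver and -0.34 in stomach (adjusted p = 0.00447, 0.00680 and 1.93e-06; adjusted p = 0.710, 0.718 and 0.527 with an estimated correlation). Under quantile normalization the medians in liver and stomach changed sign, to -0.0915 and 0.0419.

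Markers of tissues near the buds were measured beside these lists. Of 39 skeletal and cardiac muscle genes 3 were lower in pancreas (median -0.28, adjusted p = 0.0171, and adjusted p = 0.222 with an estimated correlation), 2 were higher and 2 lower in liver (adjusted p = 0.0632), and 3 were higher in stomach (adjusted p = 0.697, with a median of -0.23 and a mean of 0.04). These were des.1.L and des.1.S, which smooth muscle also expresses, and ckm.L, whose 2 other probe sets had the opposite sign for a called pair of organs. Of 8 intestine genes the peptidase gene anpep.L was 11.4-fold higher in pancreas than in liver and 10.1-fold higher than in stomach, myo1a.L was lower in pancreas and higher in liver, and fabp2.L was higher in stomach. The list's adjusted p were 0.164, 0.713 and 0.312. Of 6 lung bud genes the surfactant gene sftpc.S, at 305 ± 9.23 in pancreas, 438 ± 58.3 in liver and 87.0 ± 30 in stomach (SD, n = 2), was lower in stomach and higher in liver against the mean of the others (list adjusted p = 0.986, 0.0632 and 0.171, and for liver 0.0436 with the replicate block and 0.242 with an estimated correlation). No member of 8 pronephros genes was called by the main limma fit, and with 16 added 1 was higher in liver. The gene pax2.L was at 93.1 ± 8.04, 76.4 ± 6.80 and 72.8 ± 3.84 in pancreas, liver and stomach (list adjusted p = 0.811, 0.422 and 0.613).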

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

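The tests that count numbered paralogs or add 16 together with the replicate block were chosen after seeing the data, and the other settings before. The F test called 3176 probe sets with log2 of the intensity plus 16, 3387 with the intensity trend and robust prior, 4180 by the methods' ANOVA unadjusted and 1 after adjustment, and 487 to 1034 with 1 array left out. Pancreas against liver called 1807 with low values left out, 1720 with 16 added, 1978 with the trend, 552 on the 4 arrays of the pair, 1 by the adjusted ANOVA with a ratio above 3, and 105 to 552 with 1 array left out. Pancreas against stomach called 2051, 2129, 2254, 731 and 1 under these settings in that order, and 0 to 731 with 1 array left out. Liver against stomach called 966 on 4 arrays, 0 by the adjusted ANOVA (3737 at an unadjusted limma p under 0.05), and 303 to 966 with 1 array left out. The prior degrees of freedom rose from 2.14 to 3.95 with low values left out, 3.89 with 16 added and 4.54 with the trend, and fewer arrays leave fewer residual ones. Other causes were not tested. For a pair, leaving out an array of the remaining organ gave the same counts as the 4 arrays of the pair alone, so it is no further check.

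Counts as genes here take each gene by its brightest probe set, and so are lower than gene counts over any probe set of a class. The pancreas class held 196 at a ratio above 2, 62 at 5, 239 by K-means, 0 by the adjusted ANOVA and 0 to 61 with 1 array left out. The liver class held 148 as genes, 0 by the adjusted ANOVA and 41 to 151 with 1 array left out. The stomach class held 190 with low values left out, 185 at a ratio above 5, 462 by K-means, 172 as genes, 0 by the adjusted ANOVA and 0 to 192 with 1 array left out. The pancreas-and-liver class held 52 with 16 added, 136 at a ratio above 2, 32 at 5, 182 by K-means, 48 as genes, 0 by the adjusted ANOVA and 0 to 55 with 1 array left out. The pancreas-and-stomach class held 38 with low values left out, 32 with 16 added, 36 at a ratio above 5, 160 by K-means, 37 as genes, 0 by the adjusted ANOVA and 13 to 65 with 1 array left out. The liver-and-stomach class held 35 with 16 added, 88 at a ratio above 2, 25 at 5, 138 by K-means, 31 as genes, 1 by the adjusted ANOVA and 0 to 20 with 1 array left out. Beside the adjusted ANOVA's counts of 0, limma's classes at an unadjusted p under 0.05 held 163, 357, 428, 129 and 124 probe sets in this order of classes. The adjusted ANOVA, at 3 residual degrees of freedom and no shared variance, called 1 probe set in all, which fixes its class counts. Between the lowest and highest of the settings that leave out an array, 108 to 113 of the 115 pancreas, 247 to 261 of the 263 liver and 271 to 292 of the 298 stomach probe sets kept a ratio above 3.

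Of 22 gene lists, camera called 12 in pancreas, 15 in liver and 13 in stomach, and fry called 9, 15 and 14. The calls of a list in different organs are not separate, since its differences cancel over the organs. With an estimated correlation camera called 0 in each. Lists with a negative estimate lost their pancreas calls too. Camera adjusted p went from 2.29e-05 to 0.176 for pancreas transcription factors (estimate -0.045) and from 0.00387 to 0.222 for endocrine genes (-0.0265). Correlation between members therefore does not account for these losses, and other causes were not tested. With 3 residual degrees of freedom this setting called no list at all, so its adjusted p cannot decide on any single list. With the replicate block the F test called 2092, the pairs 1055, 1289 and 1570, the classes 118, 275, 273, 87, 76 and 62, and 13, 14 and 13 lists. The block ended 26 of the 267 calls on named genes, whose adjusted p then lay between 0.0503 and 0.0797, and changed 4 list calls. With 1 array left out, 103 to 182 of the 267 calls on named genes ended, 127 without pancreas replicate 1, 103 without pancreas replicate 2, 134 and 104 without liver replicates 1 and 2, and 182 and 133 without stomach replicates 1 and 2. No call on a named gene changed direction with the block, 1 array left out, a common median, quantile normalization, 16 added or the trend. With low values left out 186 of the calls could be compared, and none changed direction. The ribosomal protein lists in liver and stomach changed sign with quantile normalization, to -0.0915 and 0.0419; the cause was not tested. Counting numbered paralogs, and adding 16 together with the block, changed 2 and 4 list calls. Without background values on the arrays, differences between probe sets under an intensity of 16 in all organs are the least certain.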

Other observations

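The genes in this paragraph were chosen after their values were seen. The creatine synthesis gene gatm.L was at 6384 and 4815 in the pancreas arrays and at 206 to 232 in the 4 others (25-fold above liver and 25.4-fold above stomach), although its other probe set differed in sign for a contrast, and gamt.S, of the same pathway, was 8.25-fold and 9.45-fold higher in pancreas. The histidine ammonia-lyase gene hal.2.S was 6.89-fold above liver and 35.3-fold above stomach, while hal.1.L had a log2 difference of 0.0372 in pancreas from the mean of the others (adjusted p = 0.966). The later histidine-degrading genes uroc1.L, amdhd1.L and ftcd.L were 22.3-fold, 14.7-fold and 19.4-fold above stomach. Above liver amdhd1.L was 2.6-fold higher, and uroc1.L and ftcd.L did not pass (adjusted p = 0.0654 and 0.0922). Among signalling genes the Notch receptor gene notch1.S was 5.92-fold and 3.35-fold, its nuclear partner rbpj.S 4.44-fold and 3.27-fold, and hes5.3.L 29.3-fold and 18.3-fold higher in pancreas than in liver and stomach. In stomach the glutathione transferase genes gsta1.L and gstp1.L were 11.7-fold and 10.4-fold above pancreas and 15.2-fold and 14.4-fold above liver, and the iodide transporter gene slc5a5.L was 27-fold and 48.4-fold higher. In liver the growth factor gene igf3.L was 27.8-fold above pancreas and 44.9-fold above stomach, and the bile acid receptor family gene nr1h5.S 18.1-fold and 24-fold. With 16 added the folds were 6.23 and 5.63 for hes5.3.L, 3.85 for notch1.S above liver, 8.92 for amdhd1.L and 14.4 for nr1h5.S above stomach, 13.1 and 16.3 for slc5a5.L and 11.5 and 13.6 for igf3.L, and without liver replicate 1 or 2 gstp1.L was 8.89-fold and 23.2-fold above liver. The folds given with all arrays for these genes had a limma adjusted p under 0.05.

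The tests in the paragraphs below were chosen after the results were seen. Genes of motile cilia were higher in stomach. A list written after the stomach class had been seen, and including genes seen in it, had 54 measured members, of which 47 were higher in stomach than in the mean of the others and none lower, with a median log2 difference of 3.13. It was 3.28 within replicate 1 and 2.77 within replicate 2. All 47 calls stayed with 16 added to each intensity, but this cannot decide on low-intensity noise. Adding 16 raised the F test's calls from 1960 to 3176, and 32 members were in the stomach class. The 22 members outside that class had a median of 1.47. Epidermis carried along, which is ciliated in tadpoles, cannot be told apart. Its 26 markers had a median of 0.156 (quartiles -0.400 and 0.790). Several were low on all arrays, such as tfap2a.L at 1.77 to 6.5 and foxi1.L at 3.82 to 9.49, so the median cannot decide. Called higher in stomach were 2 markers. These 2 were far higher there, fucolectin.S at 3395 and 2112 against 136 to 218 elsewhere and krt12.5.S at 237 and 268 against 8.37 to 25.3. Lung bud cannot be told apart. The gene sftpc.S had a log2 difference of -2.11, at 108 and 65.8 in the stomach arrays, 305 in pancreas and 438 in liver. But it is 1 marker, and no lung was measured, so a lung share in stomach cannot be sized. Ciliated cells of the stomach epithelium or adjoining gullet also stay open and were not tested.

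Liver-enriched genes were higher in pancreas replicate 1 than in replicate 2. Over the 240 liver-enriched probe sets outside the named genes the median log2 ratio was 0.235, and 174 were above 0. Scaling of the arrays at low intensity is argued against, as 0 of 10000 random lists matched on pancreas intensity had a median as high. A difference shared by all organs of an isolation cannot be told apart. The same probe sets had a median of 0.364 between the liver arrays (quartiles 0.0976 and 0.607), which goes with it. However, the 95th percentile was also higher in liver replicate 1 (1531 against 1426). Between the stomach arrays the median was 0.0653, with 40 of them under an intensity of 16, and 0.175 for the 89 over 100 there (quartiles -0.199 and 0.552), against 0.303 in pancreas. Liver tissue carried with pancreas replicate 1 may contribute. The gap in linear intensity rose with the liver level (Spearman rho 0.603 across probe sets, which are not independent). A proportional difference between the arrays would also widen the gap for brighter probe sets, so the rise does not single out carried tissue. The gap was 1.70% of the liver level in median (quartiles 0.472% and 3.09%) for the 109 with a liver intensity over 1000. The median of 0.235 was below the 0.5 set for this test after the results were seen. A small share need not reach 0.5, so missing it decides nothing. Carried liver tissue therefore cannot be told apart from a real difference between the buds isolated.

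Stomach-enriched genes were in turn higher in pancreas replicate 2 than in replicate 1. Over the 267 stomach-enriched probe sets outside the named genes the median log2 ratio was 0.197, and 168 were above 0. Of 10000 matched random lists 2 had a median as high, which argues against scaling at low intensity. A difference shared by all organs is argued against only at the intensities of the stomach arrays. There the same probe sets were lower in replicate 2 (median -0.453, quartiles -0.689 and -0.0984). The 95th percentile was also lower in stomach replicate 2 (1243 against 1421), so the drop is not free of scaling. For the 58 with a liver intensity over 100, the median between the liver arrays was -0.0411 (quartiles -0.452 and 0.411). Stomach tissue carried with pancreas replicate 2 may contribute, with a Spearman rho of 0.328 between the gap in linear intensity and the stomach level. A proportional difference between the arrays could give such a rho too, so it does not single out carried tissue. The median gap was 2.36% for the 43 probe sets over 1000, whose quartiles of -1.75% and 5.10% span 0. The gene lists went both ways. Of the 22 stomach epithelium genes 11 were higher in each pancreas array, and 7 of the 10 called higher in stomach were higher in replicate 2. Of the 14 smooth muscle genes called higher in stomach, 10 were higher in replicate 1, with acta2.L at 881 against 484. The pancreas has its own level of these genes, which would hide a small share. The median of 0.197 was again below 0.5, which a small share need not reach. Stomach tissue therefore cannot be told apart from a real difference between the buds isolated.

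Pancreatic transcripts in the stomach arrays were at unequal shares of their pancreas level. The stomach arrays held 13.2% and 16.2% of the pancreas intensity of ctrb1.L, 3.51% and 4.43% of ctrl.L, 1.40% and 1.88% of cpa1.L, 1.00% and 1.27% of cpb1.S, 0.562% and 1.42% of ins.S and 1.25% and 2.00% of ins.L. The liver arrays held 0.686% and 1.80% of ctrb1.L, 0.396% and 0.497% of ctrl.L, 0.236% and 0.186% of cpa1.L, 0.795% and 0.726% of cpb1.S, 0.861% and 0.702% of ins.S and 1.58% and 1.81% of ins.L. Both pancreas arrays had their highest intensity at ctrb1.L, so saturation is not excluded for its shares, nor for those of ctrl.L, at 20980 and 14810. The liver shares of cpa1.L and cpb1.S rest on intensities of 19.8 to 25.2, without background values.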
